A study of Mus musculus with 2 samples.

How the data were processed

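Poly(A) RNA was sequenced from sorted effector regulatory T cells of 2 mouse genotypes on a C57BL/6 background, with 1 library of Nrn1+/- cells and 1 library of Nrn1-/- cells. Per the labels' protocols, cells were sorted on a FACSAria Fusion and kept in an RNA preservative. RNA was then extracted with a column kit, and messenger RNA was selected on oligo-dT beads and made into randomly primed NEBNext Ultra libraries, which per the series' design text were run on a NextSeq500. Groups were taken from the genotype labels. The labels do not say how many mice each library came from.

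The deposited values are FPKM, computed by the authors per gene. The file headers name the sample but no unit, so the unit was taken from the values, which are not whole, do not sum to 1000000, and in single-transcript genes step with transcript length, and from Cuffnorm, which the submitters' processing notes name. Those notes also name TopHat, Cuffdiff and FastQC without versions or roles, and the builds mm10 and GRCm38. The gene annotation, any filter and any scaling between libraries are not given in the sources used here. Cuffnorm can scale libraries to each other, so differences may depend on a step that cannot be seen, and 3 other scalings were tried for that reason. FPKM also divides by a transcript's effective length, which makes values of very short RNAs unstable. Snord19 was listed at 0 FPKM in the Nrn1+/- library and at 71090.6 FPKM in the Nrn1-/- library, and the FPKM of all genes summed to 645876 and 790935. Protein-coding genes made up 91.8% and 81.9% of these sums, and the 10 highest rows 8.06% and 17.6%. An exact 0 was read only as listed at 0, since all 37 mitochondrial genome rows carried it.

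Each file held 46511 gene rows with 46398 distinct symbols. The 82 symbols with several rows were summed. Positions and gene identities came from GENCODE M21 on GRCm38, matched by gene identifier without its version, and 46000 identifiers matched. Depth was estimated from low values of genes with a single annotated transcript: FPKM times transcript length less 230 bases fell within 0.1 of whole multiples of 0.0192 FPKM times kilobase for 99.3% of 865 genes in the Nrn1+/- library, and of 0.025 for 98.7% of 867 genes in the Nrn1-/- library, where chance gives 20%. If each library was divided by its own total, this implied 1.30 times as many fragments in the Nrn1+/- library. If the libraries were scaled to each other, 1.30 is a ratio of scaling factors instead. The recovered depth covers counting error only, since fragments without molecular identifiers are not independent molecules. Because the values are FPKM and no table of reads was used, no read-based test was applied and the planned option for such a table was not needed.

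For each gene the ratio was log2((Nrn1-/- + 1)/(Nrn1+/- + 1)) with a pseudocount of 1 FPKM, which understates the difference of low genes. The FPKM ratios quoted as folds carry no pseudocount, while the 2-fold and 1.5-fold thresholds apply to the log2 ratio. Genes with a mean of at least 1 FPKM were tested, which left 12344. Before the data were examined, 38 gene lists were fixed. The median log2 ratio of a list with at least 5 such members was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called when it lay outside percentiles 2.5 to 97.5. Percentile 0 means that no random list had a median as low, and 100 that none had one as high. With 1 library per genotype no single gene was tested and no library could be left out. Tested on simulated data over the 12344 genes, lists of 20 genes with no shift were called in 2.5% of 200 cases. Those shifted by 0.25 were called in 82% and those shifted by 0.5 in 100%. Members of these lists were drawn independently, so the rates do not carry over to lists of genes regulated together. Known fold changes given to 200 simulated genes returned the log2 ratio that the same formula with its pseudocount gives, which checks the calculation only. Of these genes 190 passed 2-fold on that scale.

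Genes were named by a rule set before the data were examined: Nrn1, the 5 sort genes, the 12 largest positive and negative log2 ratios at a mean of at least 5 FPKM with several classes of symbols left out, and 3 members per list with any further member of lists of up to 20 genes given with both values. The rule for the largest ratios returned 5 protein-coding genes among the 12 higher and 2 among the 12 lower, the others being short RNAs, a pseudogene and unclassified transcripts. The 7 other higher genes were AL596185.1, AF357399, AC137871.1, AC155839.1, RP24-141D20.1, AC156028.2 and AC122428.1. The 10 other lower genes were AC073562.1, Rny3, AC161199.1, AC160635.1, AC026385.1, SCARNA15, AC137678.1, RP23-317I8.1, AC122804.1 and Rps3a3. The report names the 12 per direction among protein-coding genes only, a choice made after the values were seen. Members that complete a count of 5 or fewer, the marker Cd79a, and Snord19 were also named after their values were seen. Some genes that the rule selects are not reported here. The main analysis was run more than once, to correct the depth estimate, which first settled on a divisor of the true step in 1 library, and to remove from an added list genes already seen.

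Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 FPKM, centring on the median ratio of genes with at least 10 FPKM, scaling by each library's upper quartile, rescaling to a sum of 1000000, 10 expression bins, a 1.5-fold threshold and, added after the data were seen, protein-coding genes only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.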

Results

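RNA sequencing compared effector regulatory T cells (effector Treg cells) of Nrn1+/- and Nrn1-/- mice, with 1 library per genotype. Regulatory T cells are CD4 T cells that express the transcription factor Foxp3 and restrain other immune cells, and the effector subset carries an activated surface phenotype. Nrn1 encodes neuritin, a small protein anchored to the cell surface that was first described in neurons. The cells were sorted as CD4+ and CD25+ with an activated, CD44-high phenotype and as positive for green fluorescent protein placed under Foxp3. The control library bears a title calling it wild type, while its genotype label gives Nrn1+/-, so the contrast reported here is heterozygous against null. Values are FPKM (fragments per kilobase of transcript, scaled to sequencing depth). The spacing of low values made 1 fragment on 1 kb worth 0.0192 FPKM in the Nrn1+/- library and 0.025 FPKM in the Nrn1-/- library. That means 1.30 times as many fragments in the Nrn1+/- library only if each library was divided by its own total, which is not known. With those steps a 2 kb transcript at 5 FPKM rested on 461 and 354 fragments, a counting error of 4.66% and 5.31%. With no replicates, no difference below has a check against the spread between animals, and no p-value is given. Differences are stated as values in these 2 libraries.

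The first comparison asks whether the targeted gene differed between the libraries as their labels say. Nrn1 (ENSMUSG00000039114.14, GRCm38 chromosome 13, 36725361 to 36735131, minus strand, 5 annotated transcripts) stood at 66.5 FPKM in the Nrn1+/- library and 4.62 FPKM in the Nrn1-/- library. This was 14.4-fold lower, 6.95% of the Nrn1+/- value, and the largest negative log2 ratio (-3.59) among the protein-coding genes tested. Which part of the gene the null allele lacks is not given in the sources used here, so the remaining 4.62 FPKM cannot be assigned to an exon. Among the genes behind the sort, Cd4 (161 and 155 FPKM) and Il2ra, which encodes CD25 (601 and 564 FPKM), had log2 ratios of -0.06 and -0.09. Foxp3 itself was at 257 FPKM in the Nrn1+/- library and 195 FPKM in the Nrn1-/- library, 1.32-fold lower. Cd44, a marker of activated T cells, was 1.29-fold higher (62.4 against 80.5 FPKM). These ratios depended on scaling: at a sum of 1000000 the log2 ratio went from 0.36 to 0.073 for Cd44, to -0.35 for Cd4, to -0.38 for Il2ra and from -0.40 to -0.69 for Foxp3. Part of that shift, here and below, comes from non-coding rows with unstable values, such as Snord19 at 0 and 71090.6 FPKM. All rows summed to 645876 FPKM in the Nrn1+/- library and 790935 in the Nrn1-/- library, but protein-coding rows to 593035 and 647545.

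The next comparison asks how widely expression differed. Of 10695 protein-coding genes with a mean of at least 1 FPKM, 129 were at least 2-fold higher and 28 at least 2-fold lower in the Nrn1-/- library, and 89.3% lay within 1.5-fold. The protein-coding genes with the largest positive log2 ratios were Scd2, a stearoyl-CoA desaturase that makes monounsaturated fatty acids (16.4 against 57.7 FPKM, 3.51-fold), and Ccnb1, the cyclin B1 of mitotic entry (17.7 against 56.2 FPKM, 3.18-fold). They were followed by Stra6, a receptor for retinol-binding protein (3.98 against 13.9 FPKM), Cdc20, an activator of the anaphase-promoting complex (28.1 against 85.6 FPKM), and Mt3, a metallothionein (24.5 against 73.8 FPKM). Plk1, Cdk1, Nek2, Ccna2 and Birc5, all genes of the mitotic cycle, were also among the 12 largest, as were Dapl1 and the cytokine gene Il9. After Nrn1, the genes with the largest negative log2 ratios were Trib3, a pseudokinase gene induced in amino acid and endoplasmic reticulum stress (28.6 against 10.5 FPKM, 2.74-fold lower), and Lars2, the mitochondrial leucyl-tRNA synthetase (331 against 127 FPKM, 2.60-fold lower). Slc7a3, a cationic amino acid transporter (9.25 against 2.98 FPKM), Nupr1, a stress-induced nuclear protein (10.8 against 3.93 FPKM), and Slc6a9, a glycine transporter (15.1 against 6.12 FPKM), came next together with Ms4a4c. The list of 12 closed with Ms4a4b (233 against 108 FPKM), Slc15a2, Trp53inp1 (64.8 against 30.6 FPKM), Crebrf and Ypel3 (178 against 86.1 FPKM).

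Over all 12344 genes, coding or not, 244 were at least 2-fold higher and 137 at least 2-fold lower. Non-coding genes gave 115 of the higher and 109 of the lower genes although only 1649 were tested, and many were short RNAs listed at 0 in one library. Across genes, which are not independent replicates, the log2 values of the libraries correlated with Pearson's r of 0.94 and Spearman's rho of 0.96, or 0.98 for both over protein-coding genes. The standard deviation of the log2 ratio over protein-coding genes was 0.38 at 1 to 5 FPKM and 0.35 above 100 FPKM. The median ratio moved with level, from -0.05 at 1 to 5 FPKM to 0.20 above 100 FPKM. The balance between higher and lower genes depended on scaling: over all genes it was 193 to 191 with upper-quartile scaling and 150 to 361 when each library was rescaled to a sum of 1000000, and over protein-coding genes it was 85 to 61 and 45 to 173. These scalings moved the log2 ratios of all genes by a median of -0.12 and -0.28, and list results below are therefore given against random lists drawn from the same scaling.

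**Figure D1:**
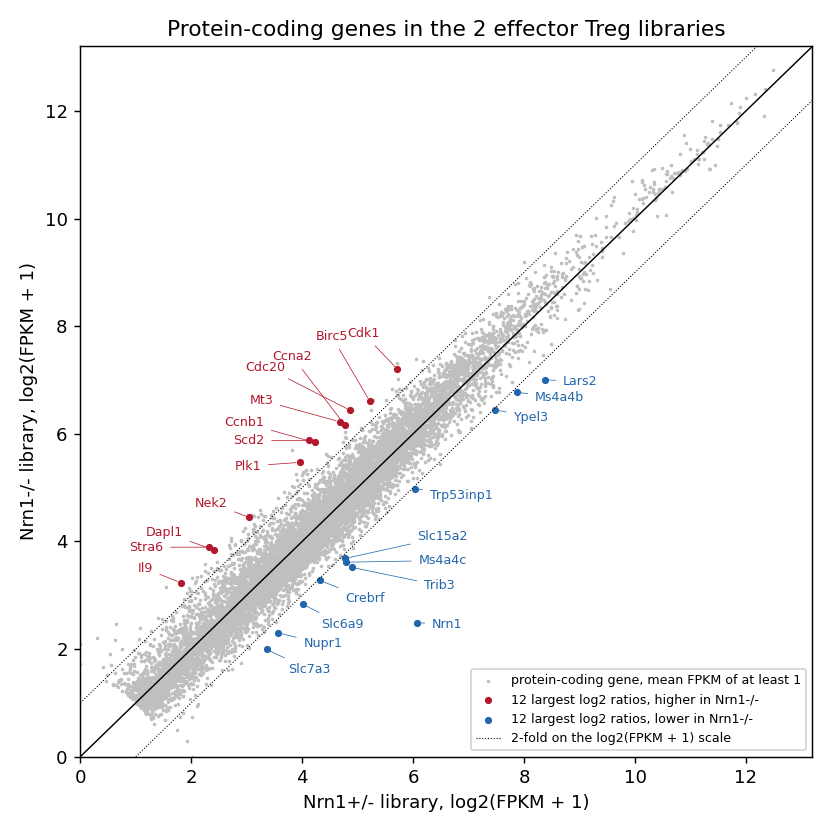
Expression of each protein-coding gene with a mean of at least 1 FPKM in the Nrn1+/- library (x axis) and the Nrn1-/- library (y axis), both as log2(FPKM + 1), with 1 library per genotype. Red and blue points are the 12 largest positive and negative log2 ratios, dotted lines mark a 2-fold difference, and Nrn1, at 66.5 against 4.62 FPKM, lies farthest below the line of equality.

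Genes of cell division were higher as a body in the Nrn1-/- library. All 32 measured genes of the G2 and M phases were at least 1.5-fold higher, with a median log2 ratio of 1.14 (2.21-fold). All 30 genes of the S phase were higher and 28 of them by at least 1.5-fold, with a median of 0.87 (1.82-fold). Among the G2 and M genes Plk1, a mitotic kinase, stood at 14.5 against 43.3 FPKM beside Ccnb1 and Cdc20. Among the S phase genes the largest ratios were those of Rrm2, a subunit of ribonucleotide reductase (65.2 against 167 FPKM), Cdc6, a replication licensing factor (10.8 against 26.9 FPKM), and Uhrf1, a factor of maintenance DNA methylation (37.0 against 86.4 FPKM). Both lists lay at percentile 100 of random lists matched on expression, whose medians centred on 0.04 and 0.09. Of the 129 protein-coding genes at least 2-fold higher, 32 belonged to these cell cycle lists, while none of the 28 lower genes did. The G2 and M genes were higher by a median of 18.7 FPKM. All 13 B cell markers under 1 FPKM on average were higher in the Nrn1-/- library as well, reaching at most 1.18 FPKM, and markers of other cells above that level are given below. Rescaling to a sum of 1000000 left 29 of the 32 G2 and M genes and 16 of the 30 S phase genes at least 1.5-fold higher.

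Biosynthetic genes differed in the same direction. All 20 genes of cholesterol and lipid synthesis were higher in the Nrn1-/- library, 10 of them at least 1.5-fold, with a median log2 ratio of 0.60 at percentile 100. Besides Scd2 these included Fdps (38.7 against 70.3 FPKM) and Idi1 (33.9 against 61.2 FPKM), enzymes of the sterol pathway. All 25 ribosome biogenesis genes were higher, 11 at least 1.5-fold (median 0.54, percentile 100), led by Nolc1 (71.9 against 120 FPKM), Dkc1 (95.5 against 155 FPKM) and Nop2 (63.1 against 102 FPKM). Of 22 glycolysis genes, 19 were higher and 9 at least 1.5-fold (median 0.41, percentile 99.96). The largest ratios there were those of Slc16a1, a lactate transporter (18.7 against 33.6 FPKM), Hk2, a hexokinase (18.2 against 32.7 FPKM), and Eno1, an enolase (328 against 561 FPKM). Of 21 genes of the unfolded protein response 16 were higher (median 0.37, percentile 99.7), and the 5 that reached 1.5-fold were Sdf2l1 (52.3 against 104 FPKM), Pdia6, Hspa5 (355 against 548 FPKM), Hsp90b1 and Hyou1, all chaperones or folding factors of the endoplasmic reticulum. The 5 lower members were Dnajb9, Herpud1, Ern1, Edem1 and Xbp1, none of them by 1.5-fold. Rescaling to a sum of 1000000 moves a list and its random lists alike, so it kept these 4 calls. It brought the medians of glycolysis to 0.13 and of the unfolded protein response to 0.076. It also left 2 cholesterol, 1 unfolded protein response and no glycolysis or ribosome biogenesis genes at least 1.5-fold higher. The unfolded protein response then had 11 genes higher and 10 lower, 3 of the latter beyond 1.5-fold.

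The nuclear genes of oxidative phosphorylation were higher for 40 of 41 members with a median log2 ratio of 0.26, but that value lay at percentile 88.1 of matched lists, so it did not stand apart from other genes of the same level, and at a sum of 1000000 it was -0.04 with 17 members higher. Cycs, encoding cytochrome c (41.9 against 69.9 FPKM), was the one member beyond 1.5-fold. Genes of fatty acid oxidation (20 measured, median 0.07, percentile 65.05) did not stand apart either, with Acsl5 at 58.5 against 88.7 FPKM the one beyond 1.5-fold. Cytosolic ribosomal protein genes are a case where median and test differ in sign: 38 of 48 were higher with a median of 0.08, yet matched lists had a median of 0.19, which put them at percentile 1.41. Their median turned negative with upper-quartile scaling (-0.054) and rescaling to a sum of 1000000 (-0.21), and the call was lost with no filter on low values (percentile 2.74) and with 10 expression bins (percentile 3.18). The 37 mitochondrial genome rows, among them the 13 genes of the fixed list, were listed at 0 in both libraries, which gives no measure of mitochondrial transcription.

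Genes that define regulatory T cells were lower. Of 19 measured Treg core genes 18 were lower in the Nrn1-/- library, with a median log2 ratio of -0.33 (1.26-fold lower) at percentile 0. Only Nt5e, the ectonucleotidase CD73 (113 against 64.2 FPKM), and Entpd1, the ectonucleotidase CD39 (40.1 against 23.6 FPKM), passed 1.5-fold. Lrrc32, the surface receptor for latent TGF-beta (173 against 116 FPKM), and Nrp1 (26.5 against 17.6 FPKM) came next. Ikzf2, the transcription factor Helios, was at 72.8 against 54.4 FPKM and Ctla4, an inhibitory receptor, at 491 against 389 FPKM. Capg, at 678 against 696 FPKM, was the one member not lower, and it was lower too after centring or with either other scaling. With a sum of 1000000, 10 of the 19 genes passed 1.5-fold.

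The suppressive mediator list, which shares several of these genes, went both ways. Its median was -0.24 at percentile 0.26, with 8 of 15 genes lower. Il10 (94.05 against 68.7 FPKM) was lower, while Gzma (5.73 against 11.01 FPKM), Gzmb (104 against 155 FPKM) and Lgals1 (357 against 523 FPKM) were higher. This call was lost with no filter on low values, where the median was -0.038 at percentile 12.4. Of the effector Treg genes 11 were higher and 11 lower (median -0.07, percentile 4.2), a balance that moved to 8 and 14 after centring and to 7 and 15 with either other scaling. Rora, a nuclear receptor (10.01 against 4.91 FPKM), was the one beyond 1.5-fold as reported, against 7 at a sum of 1000000. Follicular regulatory T cell genes did not stand apart (11 measured, median -0.03, percentile 23.02), with Il1r2 at 45.6 against 32.3 FPKM as the largest ratio.

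Genes common to T cells lay lower than matched genes (12 of 18 lower, median -0.19, percentile 0.01), led by the costimulatory receptor gene Cd27 (156 against 103 FPKM), Cd2 (635 against 465 FPKM) and Cd3g (250 against 186 FPKM), while Thy1 was at 207 against 265 FPKM. The JAK-STAT5 and IL-2 response list had 12 of 18 genes lower (median -0.11, percentile 0.5). Its largest ratio was that of the survival gene Bcl2 (43.9 against 25.5 FPKM), whereas Bcl2l1, another survival gene, stood at 105 against 140 FPKM. The anergy and exhaustion list, which holds Nrn1 itself, had 15 of 20 genes lower (median -0.20, percentile 0.2). Without Nrn1 the median was -0.18 at percentile 0.5, with Nt5e and Dgka, a diacylglycerol kinase (143 against 92.9 FPKM), beyond 1.5-fold lower. At a sum of 1000000 the genes beyond 1.5-fold lower went from 1 to 5 for the T cell list, from 1 to 4 for the JAK-STAT5 list and from 3 to 5 for the anergy list with Nrn1.

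Interferon response genes had the lowest median of the 34 lists ranked. Of 26 measured, 24 were lower and 11 at least 1.5-fold, with a median log2 ratio of -0.55 (1.46-fold lower) at percentile 0. Ifit3 (44.9 against 22.2 FPKM), Oasl2 (26.1 against 13.5 FPKM) and Ifit1 (12.4 against 6.19 FPKM), all antiviral effector genes, had the largest ratios. Genes of naive and central memory T cells followed, with 13 of 16 lower (median -0.40, percentile 0.02). Of these, 4 were beyond 1.5-fold lower, among them Bcl2, Klf2 (75.7 against 47.4 FPKM), a transcription factor of quiescence and trafficking, and Il7r, the IL-7 receptor (20.4 against 13.24 FPKM). Tcf7 (72.6 against 64.3 FPKM) and Lef1 (69.5 against 73.3 FPKM), transcription factors of resting T cells, differed little, and Dapl1 ran the other way at 4.34 against 13.3 FPKM. Chemokine and homing receptor genes were lower for 12 of 16 (median -0.20, percentile 0.84). Cxcr4 (25.8 against 14.3 FPKM) and Cxcr6 (22.1 against 13.7 FPKM) were beyond 1.5-fold, while Ccr8 (106 against 150 FPKM) and Ccr4 (42.2 against 55.2 FPKM) were higher. Genes beyond 1.5-fold lower went from 11 to 15 with upper-quartile scaling and 20 at a sum of 1000000 for the interferon list, from 4 to 8 and 9 for the naive list and from 2 to 5 and 6 for the chemokine list.

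T helper cytokine genes were divided. Il9 (2.51 against 8.39 FPKM), Il3 (6.20 against 13.1 FPKM), Ifng (27.7 against 54.9 FPKM) and Il13 (16.3 against 25.4 FPKM) were at least 1.5-fold higher in the Nrn1-/- library. The interleukin-17 genes Il17f (14.3 against 7.02 FPKM) and Il17a (33.6 against 19.6 FPKM) were at least 1.5-fold lower. Il4 (12.5 and 12.3 FPKM) differed by 1.02-fold. With 10 of 16 genes higher the median was 0.26 at percentile 98.7, and it turned to -0.022 after rescaling to a sum of 1000000. The list was still called higher there, a call that could hardly change because matched lists move alike.

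The list of mTORC1 and amino acid response genes had a median log2 ratio of -0.19 at percentile 0.04, with 13 of 23 genes lower. Those beyond 1.5-fold were Trib3, Chac1, a glutathione-degrading enzyme (10.5 against 4.63 FPKM), Ddit3, the transcription factor CHOP (70.6 against 37.4 FPKM), and Ddit4 (122 against 78.1 FPKM), an inhibitor of mTORC1. At a sum of 1000000, 21 of the 23 were lower and 8 beyond 1.5-fold. Amino acid transporter genes as a list did not stand apart (18 measured, median -0.03, percentile 23.3), although Slc6a9 and Slc1a4 (10.2 against 6.18 FPKM) were beyond 1.5-fold lower and Slc43a3 (24.3 against 45.9 FPKM) beyond 1.5-fold higher. Slc7a5 and Slc1a5, carriers of large neutral amino acids and glutamine, stood at 119 and 120 FPKM and at 240 and 234 FPKM.

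Ion transport and receptor genes, included because neuritin is known from neurons, showed few differences. Of 20 potassium channel genes 10 were measured (median 0.13, percentile 84.5), and Kcnk5 (5.11 against 8.61 FPKM) was the one beyond 1.5-fold. The sodium, calcium and chloride transport list had 21 of 31 genes lower with a median of -0.13 at percentile 2.74, just short of a call, and it passed under 6 alternatives, such as upper-quartile scaling (percentile 2.08). Atp1b1, a sodium pump subunit (15.4 against 9.53 FPKM), was beyond 1.5-fold lower, and the calcium pump gene Atp2a2 was at 84.8 against 122 FPKM. Of 29 genes of glutamate receptors and associated proteins 8 reached 1 FPKM (median -0.03, percentile 25.7), with Shisa5 at 1511 against 1072 FPKM the largest ratio. Neuritin family and neuronal growth genes gave no call, either with Nrn1 (6 measured, median -0.13, percentile 20.9) or without it (5 measured, median -0.0040, percentile 51.1), with Igf1r at 15.8 against 10.7 FPKM.

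The NF-kB, apoptosis, p53 and immediate early lists were not called. NF-kB targets had 9 of 18 genes on each side (median -0.05, percentile 6.15), with Bcl2a1d at 23.6 against 33.7 FPKM. That balance was 8 higher and 10 lower after centring, 5 and 13 with upper-quartile scaling and 3 and 15 at a sum of 1000000. Apoptosis genes (19 measured, median -0.02, percentile 28.2) included 3 beyond 1.5-fold higher, among them Cycs and Casp6 (27.9 against 45.2 FPKM). At a sum of 1000000 no apoptosis gene was, while 15 of the 19 were lower and 4 of those passed 1.5-fold. Of 16 p53 targets 13 were lower (median -0.10, percentile 5.26), with Trp53inp1 the one beyond 1.5-fold. Immediate early and dissociation stress genes, a check on handling, had a median of -0.03 at percentile 8.38, with the heat shock genes Hsp90aa1 (186 against 341 FPKM) and Hsph1 (56.4 against 94.7 FPKM) higher and Dusp1 (24.9 against 16.7 FPKM) lower. At a sum of 1000000 the median of that list was -0.32, with 16 of 20 genes lower, 6 of them beyond 1.5-fold, and none beyond 1.5-fold higher. With no filter on low values that list was called lower (-0.18, percentile 0.26).

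Markers of cells outside the gate gave no call. The lists for CD8 and cytotoxic T cells (6 measured, median 0.13, percentile 80.3) and natural killer cells (5 measured, median 0.11, percentile 81.0) shared Gzma as the one gene beyond 1.5-fold. The B and plasma cell list (5 measured, median 0.07, percentile 65.8) held Sdc1 (0.97 against 2.62 FPKM) and the light chain gene Igkc (11.4 against 18.1 FPKM) beyond 1.5-fold higher, while Ighm was at 229 against 180 FPKM. With no filter on low values the B cell list was called higher (median 0.22, percentile 99.99), at levels such as 0.55 against 1.16 FPKM for Cd79a. Myeloid and dendritic cell genes were lower for 7 of 9 (median -0.09, percentile 12.7), among them H2-Ab1 (29.4 against 20.05 FPKM) and H2-Aa (32.3 against 22.5 FPKM). Lists with under 5 measured genes received no percentile. The erythroid and platelet list had Car2 (2.97 against 5.15 FPKM) and Itga2b (2.34 against 1.18 FPKM), the stromal and endothelial list had Pecam1 (34.6 against 24.6 FPKM) and Epcam (16.3 against 12.2 FPKM), and of the sex-linked genes only Xist was measured (143 against 139 FPKM). The Y-linked genes Uty (0.036 and 0.093 FPKM), Kdm5d (0.044 and 0.024), Ddx3y (0.020 and 0) and Eif2s3y (0 and 0) were at the floor. With Xist this is the pattern of female cells in both libraries.

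**Figure D2:**
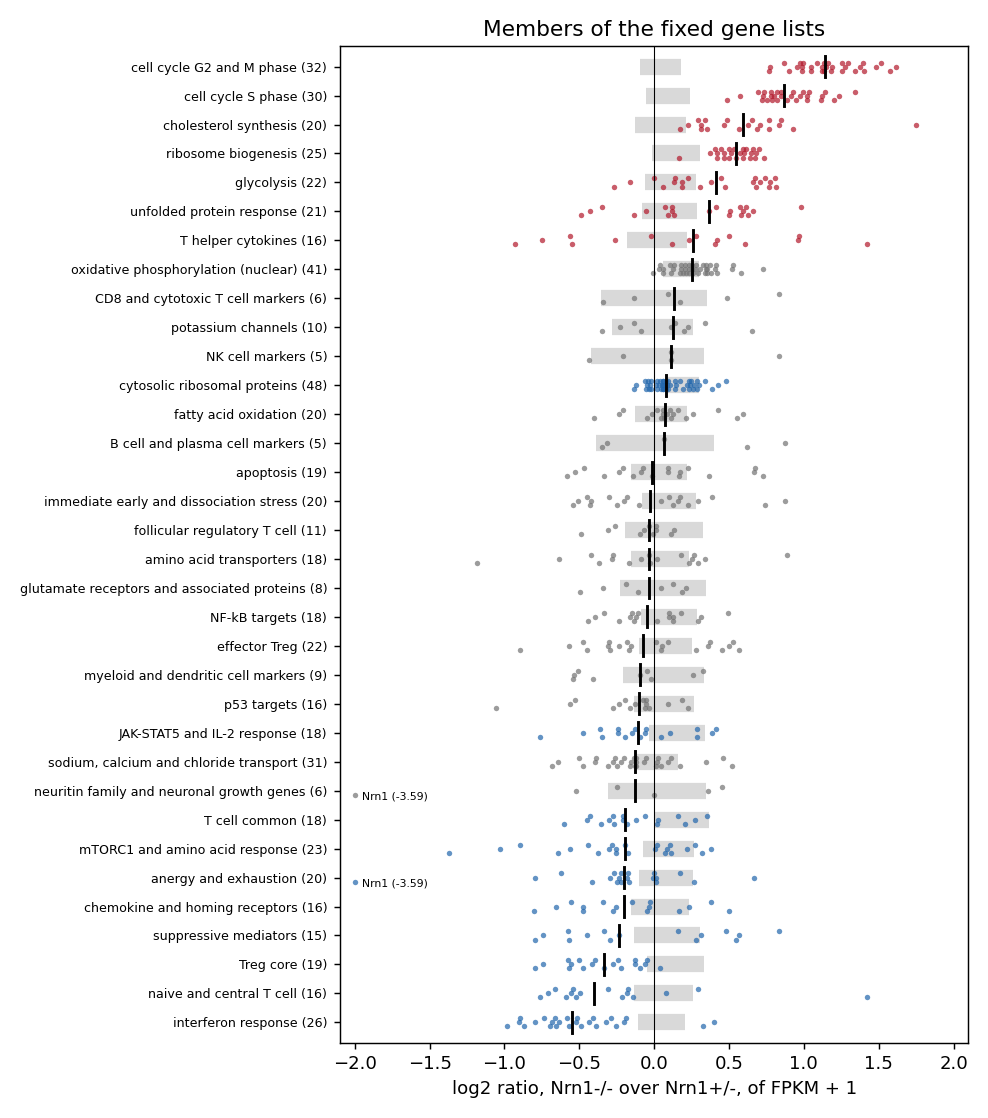
Log2 ratio (Nrn1-/- over Nrn1+/-) of each measured member (points) of the 34 gene lists ranked, with the list median (black bar) and the central 95% of medians of 10000 random lists matched on expression (grey band). Numbers in brackets are measured genes, red and blue lists lie above and below their band, and Nrn1 is drawn at the left edge with its value of -3.59; the G2 and M phase list has a median of 1.14 and the interferon response list of -0.55, both for the FPKM values as given, and the median signs of the T helper cytokine and cytosolic ribosomal protein lists turn when libraries are rescaled to a sum of 1000000.

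Of the 34 lists ranked, 7 were called higher and 10 lower, where 1.7 calls were expected by chance if lists were independent. Among the lists not called, the medians of fatty acid oxidation, potassium channels, CD8, natural killer and B cell markers were above 0 as reported and below 0 after rescaling to a sum of 1000000. Genes within a list are regulated together and the lists share members, so a percentile describes these 2 libraries and is not a test of genotype.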

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

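The restriction to protein-coding genes was chosen after the data were seen. Nrn1 and the correlation between libraries kept their direction and size under the alternatives run for them, with log2 ratios of Nrn1 from -3.59 to -3.93 and r from 0.90 to 0.98. The 17 list calls were kept under 7 alternatives and partly lost under 2. With no filter on low values the suppressive mediators (-0.038) and cytosolic ribosomal proteins lost theirs, and with 10 expression bins the latter did. Centring, upper-quartile scaling and the sum of 1000000 are among the 7. They move a list and its random lists alike, so they could hardly change a call. The sodium, calcium and chloride transport list was gained under 6 alternatives. Counts depended on the setting: genes at least 2-fold lower numbered 137 as reported, 229 with a pseudocount of 0.1 and 74 at a minimum of 5 FPKM. Counts were 150 higher and 361 lower with a sum of 1000000, 926 and 651 at 1.5-fold, where a lower threshold passes more genes, and 129 and 28 among protein-coding genes, where fewer genes are tested. A minimum of 5 FPKM also tests fewer genes (9439), and a smaller pseudocount makes every log2 ratio larger in size. Rescaling to a sum of 1000000 moves the ratios by the median shift given below.

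Scalings shift every ratio by construction, by a median of -0.06 for centring, -0.12 for upper-quartile scaling and -0.28 for a sum of 1000000, a sum to which Snord19 adds in the Nrn1-/- library alone. Centring brought cytosolic ribosomal proteins to 0.012. Higher lists shrank, to these medians under upper-quartile scaling and a sum of 1000000: G2 and M phase 1.02 and 0.88, S phase 0.74 and 0.61, cholesterol synthesis 0.47 and 0.32, ribosome biogenesis 0.42 and 0.26, glycolysis 0.28 and 0.13, unfolded protein response 0.23 and 0.076. T helper cytokines went to 0.13 and then turned to -0.022, and cytosolic ribosomal proteins turned to -0.054 and -0.21. Lower lists moved further down: interferon response -0.68 and -0.84, naive and central T cell -0.53 and -0.69, Treg core -0.47 and -0.63, suppressive mediators -0.37 and -0.53, anergy and exhaustion -0.33 and -0.49, T cell common -0.33 and -0.48, mTORC1 and amino acid response -0.32 and -0.48, chemokine and homing receptors -0.32 and -0.48, JAK-STAT5 -0.24 and -0.40.

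Leaving out short or failed genes by length or status was not run, since the files give neither, and the read-based alternative was not run because the values are FPKM. No paired analysis was possible because each genotype has 1 library. Depth limits low genes: a 2 kb transcript at 1 FPKM rests on 92.2 and 70.8 fragments, a counting error of 10.4% and 11.9%, and no setting measures the difference between animals.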

Other observations

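All lists in this and the next paragraph were added after the data were seen. Protein-handling genes were higher in the Nrn1-/- library together with the biosynthetic lists. All 27 proteasome subunit genes measured were higher, with a median log2 ratio of 0.34 at percentile 98.3 (0.05 after rescaling to a sum of 1000000), though none reached 1.5-fold, and Psmd12 stood at 57.8 against 83.7 FPKM. Of 15 chaperonin and prefoldin genes 14 were higher (median 0.49 at percentile 99.8, and 0.20 after rescaling to a sum of 1000000). The mitochondrial chaperonin gene Hspd1 stood at 236 against 443 FPKM and the cytosolic chaperonin subunit Cct8 at 274 against 429 FPKM. Aminoacyl-tRNA synthetase genes did not stand apart (20 measured, median 0.13, percentile 43.0).

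Genes of MHC class I presentation and of the GIMAP family were lower. Of 15 genes of MHC class I presentation 13 were lower (median -0.13, percentile 0.39), among them Nlrc5, the transcriptional activator of that pathway (137 against 98.1 FPKM), H2-K1 (2607 against 1936 FPKM) and B2m (2586 against 1946 FPKM). All 8 measured genes of the GIMAP family, GTPases of lymphocytes, were lower (median -0.37, percentile 0.07), with Gimap3 at 427 against 278 FPKM. The nuclear non-coding RNAs Malat1 (227 against 141 FPKM) and Neat1 (153 against 79.0 FPKM) were lower as well, both singled out after their values were seen. Percentiles in these paragraphs describe the 2 libraries and test no genotype.

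In the weighing that follows, the tests of scaling, of other dividing cells, of both Treg core explanations and of the stress targets were chosen after the result was seen, while those of GC content and length, of the ribosomal sequences and of the quiescence genes were written down first. The tests of other dividing cells and of the share of Foxp3-expressing cells replaced earlier ones on 7 and 6 genes picked by hand, and their bounds were set with the values known. With 1 library per genotype, genotype cannot be separated from the animal, the sort or the library preparation in any of them, and biological explanations by genotype stay untested.

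The first pattern is the higher level of cell cycle genes. Scaling between libraries changes its size but does not account for all of it, since the G2 and M phase median of 1.14 was 1.08 after centring and 0.88 at a sum of 1000000, where that of the S phase went from 0.87 to 0.61. Both stayed at percentile 100, which a scaling could hardly change because it moves random lists alike. Removing the median ratio of each bin of GC content and transcript length left the G2 and M median at 1.13. Dividing B, plasma, cytotoxic T or myeloid cells would bring the markers of their type with them. Over all members of the 3 marker lists the highest median increase was 0.35 FPKM, that of the CD8 and cytotoxic list, against 18.7 FPKM for the G2 and M genes. A median over markers of several cell types, as in the myeloid list, can stay low when 1 type enters, so it cannot exclude that. The FPKM gained per cell may also differ between these gene sets, and conventional CD4 T cells are in none of the 3 lists. Single members did rise, Nkg7 (81.5 against 115 FPKM) and Bst2 (163 against 204 FPKM) by more than 18.7 FPKM and Igkc by 6.68 FPKM, so an admixture is not ruled out. A larger share of dividing cells in the Nrn1-/- sample, whether from genotype or from animal or sort, stays open as a hypothesis.

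The second pattern is the lower level of Treg core genes. Resting conventional T cells in the sort would raise genes of naive and central T cells, whose median was -0.40 instead. A shift toward dividing cells may lower the same genes and hide such an admixture, so this median cannot exclude it. A lower share of Foxp3-expressing cells, replaced by activated conventional T cells, stays open, although the gate on Foxp3 reporter fluorescence should remove the latter. Dilution alone would lower no core gene further than Foxp3 (log2 ratio -0.40), yet 8 of the 19 lay below it, down to -0.80 for Nt5e. That distance of 0.40 is within 2 standard deviations of the ratios of protein-coding genes above 100 FPKM (0.35 each). Such a spread across genes may hold real differences and is not the error of 1 gene's ratio. With 1 library per genotype that error between animals is unknown. The distance therefore cannot tell dilution from a lower level within each cell.

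The third pattern is Lars2, lower at 331 against 127 FPKM. Reads shared with the mitochondrial ribosomal gene mt-Rnr2 were weighed because mitochondrial genes were listed at 0. The longest identical stretch between them was 12 bases, no longer than the 14 bases found for Nrn1, which speaks against that route. Nuclear ribosomal RNA reads that align to Lars2 could not be settled: the longest shared stretch with a ribosomal RNA-like gene was 13 bases, under the 20 set beforehand as ruling it out, but that bound was wrong because the annotation searched has no ribosomal RNA transcript longer than 1849 bases, so the large nuclear ribosomal RNA was never searched. Gm26917, the one ribosomal RNA-like gene listed, was lower too (253 against 109 FPKM, log2 ratio -1.21), which the explanation would need.

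A further hypothesis was that Trib3, Chac1 and Ddit3 mark lower expression of integrated stress response targets as a group. A second list of such targets, which shares no gene with the fixed lists, lay at percentile 0 (14 of 16 lower, median -0.43), with Atf5 at 28.3 against 14.6 FPKM and Pck2 at 34.5 against 21.3 FPKM. Genes already seen were first in that list and were removed after its first result, which was also percentile 0. This describes a lower level of these targets in the Nrn1-/- library, not of the stress response as a whole. The aminoacyl-tRNA synthetase genes, several of them targets of the same response, did not follow. Of the mTORC1 and amino acid response genes 13 were lower and 10 higher, the latter including Phgdh (224 against 292 FPKM) and Psat1 (148 against 179 FPKM). The unfolded protein response list was called higher (median 0.37, percentile 99.7).

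The last hypothesis was that Klf2, S1pr1 and Il7r mark lower expression of quiescence and FOXO target genes as a group. A second list outside the fixed lists lay at percentile 0, with 19 of 20 genes lower and a median of -0.50, including Tsc22d3 (24.7 against 12.4 FPKM), Txnip (130 against 68.3 FPKM) and the cell cycle inhibitor gene Cdkn1b (66.2 against 35.0 FPKM). Ypel3 had been seen before, and without it the median was -0.43, again at percentile 0. The result may reflect the same shift toward dividing cells as the cell cycle lists, and whether the quiescence genes differ beyond that was not tested.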
